A study of Mus musculus with 12 samples.

How the data were processed

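The deposited table held 45101 probe sets on 12 mouse arrays, 1 column per array. Per the labels the samples were pre-B cells from mouse bone marrow that carried a C/EBPα-ER-GFP retrovirus, sorted for GFP, grown again on stromal cells, given b-Est or EtOH and sorted for GFP once more at each time, plus cultured macrophages, and RNA was extracted with Trizol. The values deposited by the authors were log2 signals made with RMA per the submitters' processing notes, which give neither a version nor settings. They were used as deposited, on the log2 scale, without further scaling in the reported fit.

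Probe sets were tied to gene symbols with the platform annotation: 34958 had 1 symbol, 932 had several and 9211 had none. Of the 64 control probe sets, 51 had no symbol or several and were left out of counts of such probe sets. Each of 18194 genes was represented by its single-gene probe set with the highest mean over the 12 arrays. Of these probe sets with 1 symbol, 34754 carried a gene found in the RefSeq gene table. Probe sets with no symbol or several entered only the alternative that tests every probe set.

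A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend), with version 1.17.8 of data.table. The spread was shared over the 6 groups, with 6 residual degrees of freedom and 4.50 prior degrees of freedom, and the median standard error of a difference between 2 groups was 0.19 on the log2 scale. With 2 arrays per group, the number of arrays limits the precision. P-values were adjusted by Benjamini and Hochberg within each of 9 comparisons, and genes with an adjusted p below 0.05 are called higher or lower. All limma tests are two-sided. The comparisons were 3, 12, 48 and 120 h of b-Est and macrophages each against vehicle, 120 h against macrophages, and each time against the one before it.

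In each comparison 34 gene lists, written from textbook knowledge, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. The fry test of limma was run beside them. The lists covered B lineage transcription factors, B lineage surface and signalling genes, V(D)J recombination, myeloid transcription factors, macrophage surface genes, lysosome, NADPH oxidase, cytokines and chemokines, Toll-like receptors, complement, MHC class II, interferon-stimulated genes, stem cell genes, primary granule and neutrophil granule genes, S phase, G2 and mitosis, Myc and ribosome biogenesis, sterol synthesis, lipid handling, glycolysis, integrins, DNA methylation and chromatin regulators, apoptosis, osteoclast genes, and genes of stromal fibroblasts, T cells, NK cells, erythroid cells, megakaryocytes, mast cells, dendritic cells, mature B cells and pluripotent cells. The reference genes used for scaling and 4 sex-linked genes were kept apart. The groups, comparisons, tests, lists, rule for named genes and all alternatives except the last 2 below were set before the data were examined.

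Genes were named by a rule: in each comparison the 10 with the largest rise and the 10 with the largest fall among called genes whose 2 same-numbered replicate differences had that sign, in every group Cebpa, Ebf1, Pax5, Spi1, Itgam, Csf1r, Lyz2, Kit, Flt3 and Cd34, and from each list up to 4 called members with the largest change, or other members with their values where fewer were called. For transient genes the 10 with the largest rise at the middle time were taken. Unnamed transcripts were passed over, and the few genes outside the rule are marked as chosen after their values were seen. Folds are 2 to the power of the log2 difference.

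Overlaps of calls were set against independence and against 100 simulations without effects that keep the shared vehicle arrays, and the position of an array is its projection on the line from the vehicle mean to the macrophage mean. The procedure was tested on simulated data with planted changes: of 67 genes given a log2 change of 0.5 it called 8, of 67 given 1 it called 45 and of 66 given 2 it called 65, with 5 false calls and 0 wrong signs. The 200 planted genes were fewer than the genes called in any real comparison. The adjustment depends on that number, so the shares recovered need not hold for the real data. Alternatives tried were quantile normalization, median centring, cyclic loess and centring on reference genes, leaving out the 40 percent of genes with the lowest mean, the mean of all probe sets of a gene, leaving out probe sets shared between transcripts, eBayes with trend and robust fitting, the replicate number as a block, only the arrays compared, a change of at least 2-fold, all probe sets singly, and leaving out each array in turn. Array weights, and the block without the second 12 h array, were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.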

Results

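RNA from mouse bone marrow pre-B cells carrying a C/EBPα-ER retrovirus was measured on 12 arrays in 6 groups of 2. C/EBPα is a transcription factor of myeloid cells, and in the fusion it is joined to a hormone receptor domain that b-Est (β-estradiol) switches on. Of the 6 groups, 1 received EtOH, the solvent of b-Est, for 3 h and is called vehicle here, 4 received b-Est for 3, 12, 48 or 120 h, and 1 consisted of cultured macrophages as the target cell type. The labels say that the cells were placed on stroma in duplicate. They do not state whether the duplicates were kept as separate cultures throughout, so every p-value measures the spread between these samples. The only vehicle group was taken at 3 h, so the later comparisons with vehicle hold both b-Est and time in culture.

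The median log2 signal of an array lay between 5.02 and 5.28, and 18194 genes were tested. Replicates correlated across genes at r = 0.971 to 0.993 (genes are not independent replicates), and with 2 arrays per group the number of arrays limits the precision. The 12 h pair had r = 0.971, a value both arrays share, against at least 0.991 in the other groups. The second 12 h array stood apart with an interquartile range of 2.53, against 2.84 to 3.18 on the other 11 arrays. The first 12 h array had the largest 3′ minus 5′ differences of the actin and Gapdh controls of all arrays, 4.22 and 3.79. Probe sets of Y-linked genes read 3.47 to 4.59, and a fold is given as at least its value where a group mean lay in or below this range, since the signal there is near background. A log2 change printed for such a gene is likewise a lower bound of its size. Replicate numbers also followed a processing run. The added poly-A control dap averaged 4.62 on the 6 arrays numbered 1 and 10.3 on the 6 numbered 2. Each run held all 6 groups, so counts from a fit with the run as a block are given beside the counts of genes. Across all genes the changes within the runs correlated at r = 0.676 to 0.973 over the 9 comparisons. The deviation of the second 12 h array correlated with the mean level of the genes at r = -0.364, so dim genes read higher on it.

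Genes that mark the B lineage and the macrophage moved in opposite directions over the course. Ebf1 (Entrez 13591), a factor that sets up the B lineage programme, had a mean log2 signal of 11.37 ± 0.32 (SD, n = 2) in vehicle, 10.18 at 3 h, 9.08 at 12 h, 6.85 at 48 h, 4.26 ± 0.70 at 120 h and 3.42 ± 0.09 in macrophages. Pax5 (Entrez 18507), which keeps cells in the B lineage, went from 7.94 ± 0.34 in vehicle to 6.10 ± 0.37 at 3 h and 5.17 ± 0.34 at 120 h. Csf1r (Entrez 12978), the receptor for macrophage colony-stimulating factor, went from 5.35 ± 0.31 in vehicle through 8.53 ± 1.13 at 12 h to 12.80 ± 0.12 at 48 h and 14.41 ± 0.05 at 120 h, beside 14.35 ± 0.10 in macrophages. Lyz2 (Entrez 17105), lysozyme of phagocytes, stood at 6.80 in vehicle, 9.44 at 12 h, 14.30 at 120 h and 14.46 in macrophages. Itgam (Entrez 16409), which encodes the Mac-1 α chain, was at 3.86 ± 0.06 in vehicle and still at 4.28 ± 0.09 at 48 h, then at 8.16 ± 0.60 at 120 h and 8.53 ± 0.68 in macrophages. Spi1 (Entrez 20375), which encodes PU.1, had a mean of 6.85 in vehicle, 8.80 at 3 h and 9.69 at 120 h. The probe set for Cebpa (Entrez 12606) read 4.07 to 4.79 on the arrays up to 48 h, near the background level, and says nothing about the retroviral construct. Its mean was 5.16 ± 0.52 at 120 h and 6.16 in macrophages. The change of 0.89 ± 0.28 at 120 h against vehicle passed, but no longer without the second vehicle array (0.69) or the first 120 h array (0.52). The progenitor genes Kit, Flt3 and Cd34 had means of 4.70, 6.06 and 3.93 at 48 h, against 4.62, 5.64 and 3.85 in vehicle. Other groups differed: Flt3 passed as higher than vehicle at 12 h, and Cd34 was higher in macrophages.

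**Figure D1:**
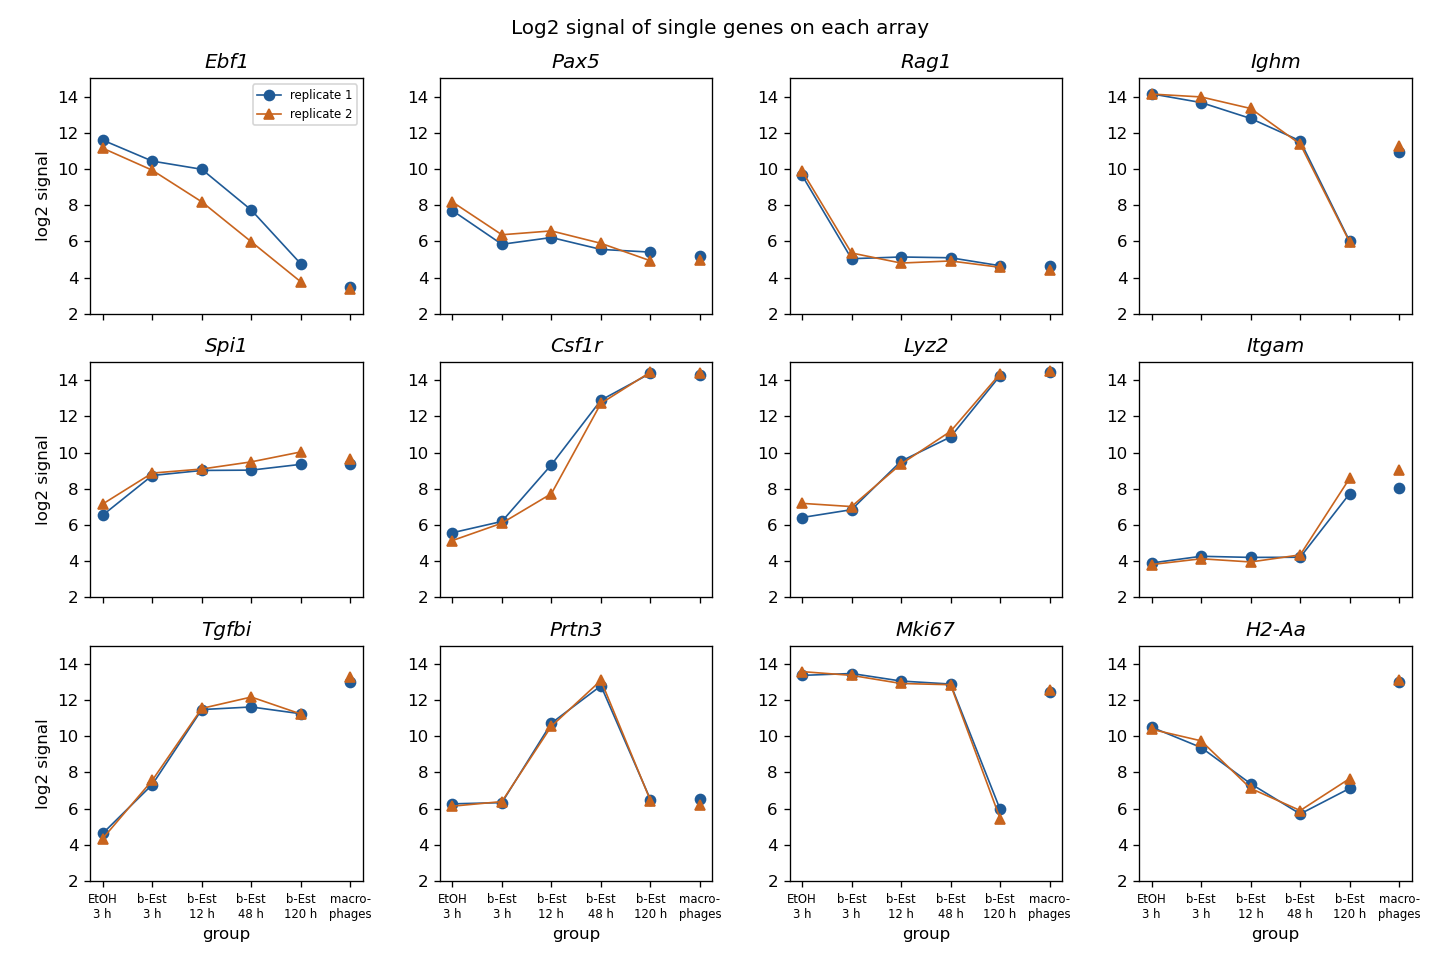
Log2 signal (vertical axes) of 12 genes on each of the 12 arrays, by group (horizontal axes), with circles for replicate 1 and triangles for replicate 2 and lines joining the vehicle and b-Est arrays of a number. Mki67 stands near 12.86 at 48 h and near 5.70 at 120 h, while Prtn3 peaks at 48 h with a mean of 12.93.

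The 3 h comparison asked which transcripts moved first, and it is the one in which b-Est and vehicle cells were taken at the same time. The transcript of Rag1 (Entrez 19373), which starts V(D)J recombination, fell 23.9-fold (log2 change -4.58 ± 0.18, SE, n = 2 arrays per group, adjusted p = 7.8e-07), from a mean of 9.78 to 5.20. Plek (Entrez 56193), a substrate of protein kinase C in blood cells, rose 27.0-fold (log2 change 4.76 ± 0.18, adjusted p = 7.8e-07). The chemokine genes Ccl3 and Ccl9 rose 10.8-fold and 7.43-fold, and Cybb, the catalytic subunit of the phagocyte oxidase, rose 8.5-fold. In all, 344 genes rose and 247 fell, 245 and 162 of them by at least 2-fold.

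Genes of the B lineage fell together at 3 h. Of 16 measured pre-B and B lineage transcription factors 9 fell, 10 adjusted over the list alone, and 7 did not pass (list test adjusted p = 4.3e-16, and adjusted p = 0.0167 with an estimated correlation). Those with the largest falls whose calls held included Id3 (-2.57), Bach2 (-2.46), a repressor of effector programmes, and Pax5 (-1.84), while Ebf1 (-1.19, adjusted p = 0.757) did not pass. Of 18 pre-B receptor and B lineage surface or signalling genes 8 fell (9 adjusted over the list alone, adjusted p = 9.7e-15, and adjusted p = 0.017 with an estimated correlation). They included Il7r, the receptor for the growth factor of early B cells (-2.80 ± 0.31), Cd72 (-2.32), Cd79b (-2.17) and Cd22 (-2.11). In the V(D)J recombination list 4 of 8 fell, 4 adjusted over the list alone (adjusted p = 2.2e-07, and adjusted p = 0.0316 with an estimated correlation), with Rag2 at -1.68 and the end-joining ligase gene Lig4 at -1.64. Other large falls were those of Mc1r (-3.95), Rragd (-3.23), Lta, which encodes lymphotoxin α (-3.17), Arpp21 (-3.05) and the chemokine receptor gene Cxcr5 (-2.84).

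Among myeloid groups at 3 h single genes rose, and most members did not pass. Spi1 rose 3.86-fold (1.95 ± 0.26), and of 21 macrophage and myeloid transcription factors 3 rose and 2 fell (4 and 4 adjusted over the list alone), the latter including Irf8 (-1.58). In the granulocyte-macrophage progenitor and primary granule list 2 of 10 rose, 3 adjusted over the list alone (adjusted p = 1.0e-04, and adjusted p = 0.104 with an estimated correlation): Gfi1, a repressor used in granulocyte formation (2.62), and Csf2rb, a shared cytokine receptor chain (2.26). Of 21 inflammatory cytokine and chemokine genes 4 rose (4 adjusted over the list alone, adjusted p = 0.00777, and adjusted p = 0.401 with an estimated correlation). Of 14 Toll-like receptor and adaptor genes 2 rose, Irak3 (2.97) and Tlr2. The call of Tlr2 was lost in 10 of the fits that left out 1 array. Among 17 integrin and adhesion genes 4 rose and 1 fell, with Vcl (2.26), Itgb3 (1.81) and Cd44 (1.38) highest. The metabolic genes Pygl (4.39), for glycogen breakdown, Dgat2 (3.97), for triglyceride synthesis, and Acot1 (3.45) rose too, as did Gpr84 (4.47), Emb (4.05), Ccn3 (3.35) and Steap4 (3.27). Macrophage surface genes were mostly not past the test, with 3 of 31 higher and 0 without the second vehicle array. Of 23 lysosome genes 0 passed with limma over all genes, 1 rose and 1 fell adjusted over the list alone, and 4 had an unadjusted p below 0.05.

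MHC class II genes and ribosome biogenesis genes were lower at 3 h as lists. Of 9 MHC class II presentation genes 2 fell and 4 fell adjusted over the list alone (adjusted p = 5.0e-07, and adjusted p = 0.052 with an estimated correlation). The 2 calls, H2-DMa (-1.16) and H2-Aa (-0.88), no longer passed when any 1 of the 4 vehicle or 3 h arrays was left out, nor after median centring or with the mean of probe sets. Of 20 Myc and ribosome biogenesis genes 3 fell, 11 adjusted over the list alone (adjusted p = 6.9e-12, and adjusted p = 0.117 with an estimated correlation), Gnl3 among them, and with 1 array left out the number went down to 1. Of the 34 lists, 11 passed at 3 h and 3 of these with an estimated correlation. With the run as a block 448 genes rose and 369 fell. A single array moved the count of 591 genes strongly: it was 344 and 331 without the first and the second vehicle array, and 290 and 281 without the first and the second 3 h array.

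By 12 h single genes of myeloid cells were far above vehicle. Tgfbi (Entrez 21810), a matrix protein gene expressed in monocytes, rose at least 129-fold (log2 change 7.01 ± 0.20, SE, n = 2 arrays per group, adjusted p = 5.3e-08), the chemokine gene Ccl9 rose 93.7-fold (6.55 ± 0.22) and Cybb rose 28.6-fold (4.84 ± 0.15). Csf1r rose 9.03-fold (3.17 ± 0.38). Rag1 (-4.81), Mpzl2 (-5.09), Tmem255a (-5.20), Enpep, a surface peptidase of early B cells (-4.20), and Bach2 (-3.89) had some of the largest falls. In all 1072 genes rose and 1851 fell, 366 and 919 of them by at least 2-fold.

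The B lineage lists stayed down at 12 h. 12 of 16 B lineage transcription factors fell (13 adjusted over the list alone, adjusted p = 4.7e-10, and adjusted p = 0.0301 with an estimated correlation), with Id3 at -4.27, Erg at -3.53 and Bcl11a at -3.53. Without the second 12 h array 10 fell. Ebf1 (-2.29 ± 0.62) passed, and no longer without the second 12 h array, where its change was -1.39, nor without the first or the second vehicle array (-2.06 and -2.51), after quantile normalization (-1.92) or after cyclic loess (-2.13). Of 18 B lineage surface and signalling genes 13 fell (13 adjusted over the list alone, adjusted p = 3.0e-11, and adjusted p = 0.0301 with an estimated correlation), and 12 without that array, among them Il7r (-3.54), Cd22 (-3.17) and Cd24a (-2.51). Of 8 V(D)J recombination genes 6 fell (7 adjusted over the list alone, adjusted p = 1.1e-07, and adjusted p = 0.0301 with an estimated correlation). Of 9 MHC class II genes 7 fell, 7 adjusted over the list alone (adjusted p = 2.2e-05, and adjusted p = 0.0694 with an estimated correlation), with H2-Aa at -3.19 and Cd74, the invariant chain, at -2.53.

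Myeloid lists rose at 12 h in part. Of 31 macrophage surface and function genes 12 rose and 19 did not pass (18 rose adjusted over the list alone, adjusted p = 7.8e-10, and adjusted p = 0.0709 with an estimated correlation), led by Tyrobp (3.37), an adaptor of activating receptors, Csf1r, Sirpa (2.95) and Clec4d (2.94). The progenitor and primary granule list had 6 of 10 higher (9 adjusted over the list alone, adjusted p = 1.2e-07, and adjusted p = 0.04 with an estimated correlation), with the granule protease genes Prtn3 (4.44) and Ctsg (2.86). Of 21 cytokine and chemokine genes 8 rose (the same number adjusted over the list alone, adjusted p = 3.8e-04, and adjusted p = 0.224 with an estimated correlation), including Ccl6 (2.85) and Il1b (2.81). Of 12 neutrophil granule genes 4 rose (6 adjusted over the list alone, adjusted p = 4.3e-04, and adjusted p = 0.0709 with an estimated correlation), Mmp8 most (4.81). Of 5 NADPH oxidase genes 3 rose (adjusted p = 0.00425, and adjusted p = 0.279 with an estimated correlation), 3 also adjusted over the list alone, with Ncf1 at 4.53. Of 21 myeloid transcription factors 4 rose, among them Spi1 (2.20) and Fosl2 (2.10), and 5 fell, among them Fos (-2.02).

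Part of the growth genes fell at 12 h, and so did the mean of the reference genes. The reference gene mean was 11.13 and 11.44 on the vehicle arrays and 10.79 and 10.94 on the 12 h arrays. The S phase list went from 10.56 and 10.69 to 9.96 and 9.93. The Myc and ribosome biogenesis list went from 10.30 and 10.66 to 9.66 and 9.75. The scaling may thus hold part of these falls. Of 26 S phase genes 10 fell (16 adjusted over the list alone, adjusted p = 2.7e-08, and adjusted p = 0.0472 with an estimated correlation), Rfc3 most (-1.52), and 11 fell without the second 12 h array. Of 20 Myc and ribosome biogenesis genes 12 fell (16 adjusted over the list alone, adjusted p = 8.8e-09, and adjusted p = 0.118 with an estimated correlation), Ncl among them (-1.31), and 8 without that array. Of 19 G2 and mitosis genes 5 fell, at the fewest 1 with 1 array left out, and the median of this list, -0.40, was 0.02 with the arrays centred on reference genes. The split of called genes at 12 h followed the scaling: 36.7% of them were higher as reported, while 1388 rose and 1146 fell after quantile normalization, 626 and 2338 after median centring, 1160 and 1233 after cyclic loess, and 6998 and 813 after centring on reference genes, which moved the median change of all genes from 0.10 to 0.52. With the run as a block 1697 rose and 2662 fell, with only the 4 arrays compared 270 and 430, and with array weights 397 and 805. The weight was 0.377 for each 12 h array, so the weights lowered the whole group and not the second array alone. Without the second 12 h array 675 rose and 1248 fell, 1923 in all, and 1585 of the 2923 genes were called in both fits, whereas without the first 12 h array 3159 rose and 2812 fell, 5971 in all, and without the second vehicle array the count was 913.

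At 48 h single genes of monocytes and of granules were strong in the bulk RNA, and many B lineage transcripts were below those of vehicle. Csf1r rose 175-fold over vehicle (log2 change 7.45 ± 0.38, SE, n = 2 arrays per group, adjusted p = 3.7e-07), Tgfbi at least 169-fold (7.40 ± 0.20), the collagenase gene Mmp8 166-fold (7.38 ± 0.26) and the granule protease gene Prtn3 (Entrez 19152) 106-fold (6.73 ± 0.16). Hp, haptoglobin, rose 105-fold and Clec4e, a C-type lectin of phagocytes, at least 80.8-fold. Ebf1 was 22.9-fold lower (-4.52 ± 0.62). In all 1363 genes rose and 1317 fell, 849 and 743 of them by at least 2-fold.

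Of 31 macrophage surface and function genes 23 rose at 48 h (23 rose adjusted over the list alone, adjusted p = 9.5e-30, and adjusted p = 0.0143 with an estimated correlation), with Tyrobp at 6.83 and Clec4d at 6.03. Of 21 myeloid transcription factors 11 rose and 2 fell (13 and 2 adjusted over the list alone, adjusted p = 5.0e-08, and adjusted p = 0.0889 with an estimated correlation). The highest were Cebpd (5.50), Tfec (4.60) and Pparg, a lipid-sensing receptor (4.21). In the progenitor and primary granule list 6 of 10 rose (6 adjusted over the list alone, adjusted p = 1.9e-08, and adjusted p = 0.0202 with an estimated correlation), with Ms4a3 at 3.86 and Csf2rb at 3.05. The neutrophil granule list had 2 of 12 higher. Of 23 lysosome genes 15 rose (15 adjusted over the list alone, adjusted p = 7.1e-11, and adjusted p = 0.0889 with an estimated correlation), led by Psap (2.91), Ctsd (2.74) and Hexa (2.61). Of 17 integrin and adhesion genes 8 rose (11 adjusted over the list alone, adjusted p = 5.6e-07, and adjusted p = 0.0202 with an estimated correlation), among them Itgal (3.08) and Itgb7 (2.92). Of 15 glycolysis genes 6 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 1.6e-04, and adjusted p = 0.154 with an estimated correlation), with Hk3 at 4.28 and the glucose transporter gene Slc2a1 at 1.98.

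Cytokine and receptor lists were partly up at 48 h. Of 21 cytokine and chemokine genes 10 rose (11 rose and 1 fell adjusted over the list alone, adjusted p = 2.1e-06, and adjusted p = 0.108 with an estimated correlation), with Il6 at 5.28 and Ccl3 at 5.50. Of 14 Toll-like receptor genes 6 rose (6 adjusted over the list alone, adjusted p = 1.5e-04, and adjusted p = 0.0573 with an estimated correlation), Tlr2 most (5.02), and 4 of 5 NADPH oxidase genes rose (adjusted p = 3.3e-05, and adjusted p = 0.108 with an estimated correlation), 4 also adjusted over the list alone. B lineage transcription factors fell in 14 of 16 cases (14 adjusted over the list alone, adjusted p = 3.3e-17, and adjusted p = 0.00749 with an estimated correlation), B lineage surface genes in 16 of 18 (16 adjusted over the list alone, adjusted p = 1.8e-20, and adjusted p = 0.00749 with an estimated correlation) and V(D)J genes in 7 of 8 (7 adjusted over the list alone, adjusted p = 1.2e-08, and adjusted p = 0.016 with an estimated correlation). The B cell surface gene Ms4a1 was at -5.06, and Bach2 at -5.13. Of 9 MHC class II genes 6 fell and 1 rose, also adjusted over the list alone (adjusted p = 3.7e-05, and adjusted p = 0.0573 with an estimated correlation). H2-Aa was at -4.64, while H2-DMa, a peptide-loading subunit, was at 2.29.

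Few proliferation genes passed the test at 48 h. Of 26 S phase genes 3 fell, 3 adjusted over the list alone (adjusted p = 3.4e-04, and adjusted p = 0.108 with an estimated correlation), and 4 of 19 G2 and mitosis genes fell. With 1 array left out these numbers went down to 1 and 0, the latter without the first vehicle array and also without the second 48 h array. Of 20 Myc and ribosome biogenesis genes 0 passed with limma over all genes or adjusted over the list alone, and 4 had an unadjusted p below 0.05. Of 34 lists 20 passed, 7 with an estimated correlation. With the run as a block 1718 genes rose and 1649 fell. The count of 2680 genes became 1653 without the second 48 h array.

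**Figure D2:**
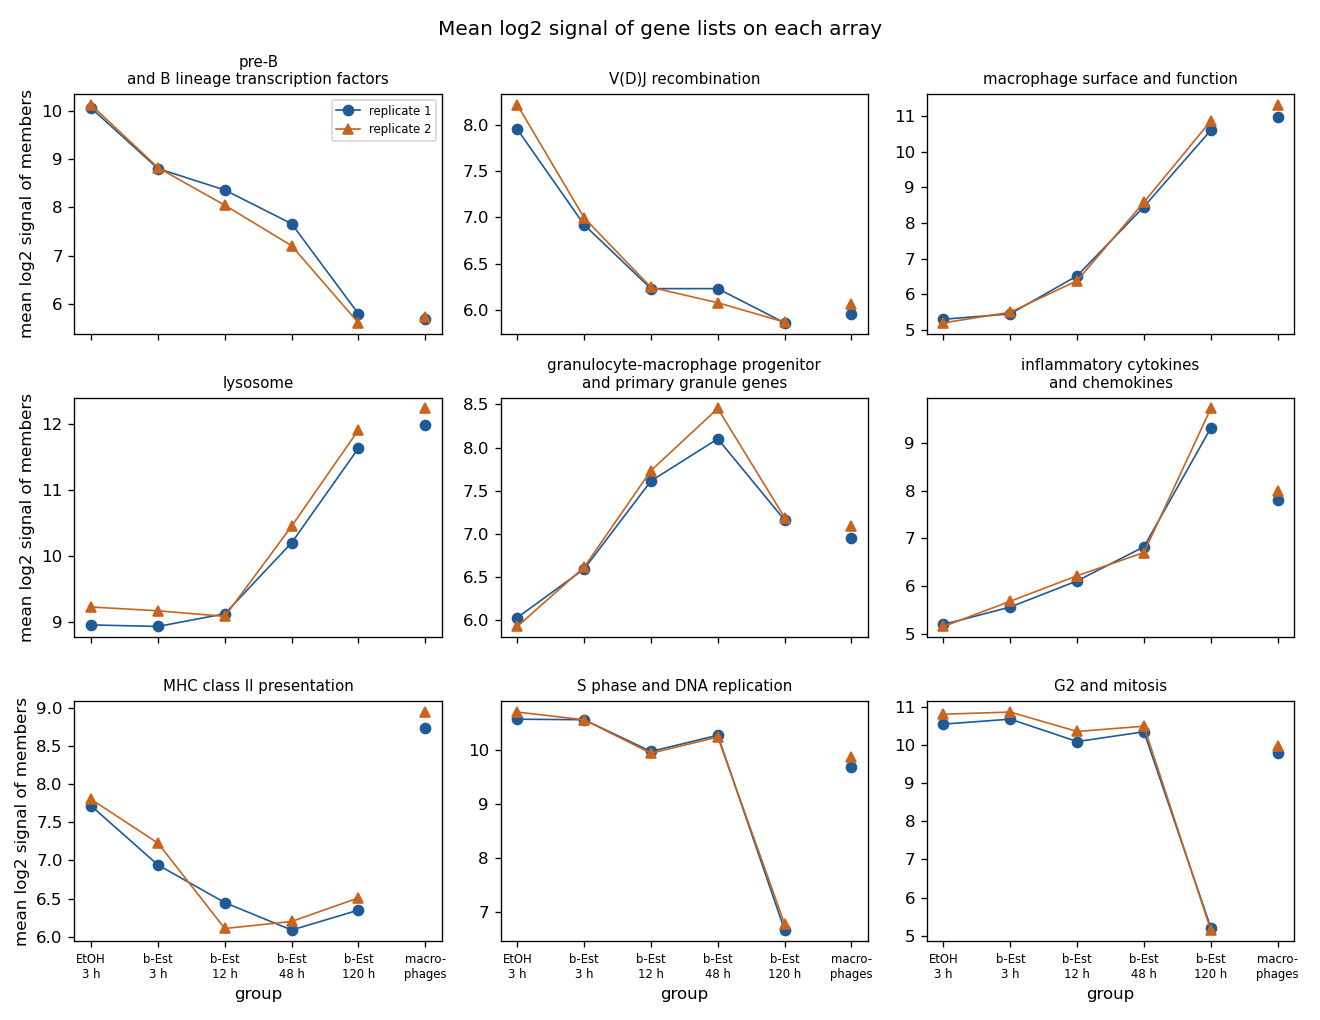
Mean log2 signal of the members (vertical axes) of 9 gene lists on each of the 12 arrays, by group (horizontal axes), with circles for replicate 1 and triangles for replicate 2. The macrophage surface list rises through 120 h, the primary granule list is highest at 48 h, and the S phase and the G2 and mitosis lists are lowest at 120 h.

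At 120 h the cells carried the highest macrophage transcripts of the course and low ones of B cells and of proliferation. Clec4n (Entrez 56620), a lectin that binds fungal sugars, rose at least 601-fold over vehicle (log2 change 9.23 ± 0.21, SE, n = 2 arrays per group, adjusted p = 5.1e-10), the neutrophil chemokine gene Cxcl2 at least 544-fold (9.09 ± 0.38), Csf1r 533-fold (9.06 ± 0.38) and the endotoxin co-receptor gene Cd14 379-fold (8.57 ± 0.31). Ighm (Entrez 16019), the μ heavy chain, was 287-fold lower (-8.17 ± 0.20), Mki67 (Entrez 17345), a marker of cycling cells, 216-fold lower (-7.76 ± 0.18) and Ebf1 at least 138-fold lower (-7.11 ± 0.62). In all 2780 genes rose and 2862 fell, 1895 and 1846 of them by at least 2-fold.

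Macrophage lists rose nearly throughout at 120 h. Of 31 macrophage surface and function genes 29 rose and 2 did not pass (29 rose adjusted over the list alone, adjusted p = 1.5e-26, and adjusted p = 0.0119 with an estimated correlation), with Clec4e at 8.96 and Clec4d at 8.56. Of 23 lysosome genes 22 rose (23 adjusted over the list alone, adjusted p = 8.5e-15, and adjusted p = 0.0374 with an estimated correlation), the protease gene Ctsl (5.27) and Npc1, for cholesterol export (4.20), among them. Of 21 myeloid transcription factors 19 rose (20 adjusted over the list alone, adjusted p = 2.0e-13, and adjusted p = 0.023 with an estimated correlation), with Cebpd at 6.27, Maf at 6.14, Mitf at 5.98 and Cebpb at 5.55. Of 21 cytokine and chemokine genes 18 rose (18 adjusted over the list alone, adjusted p = 4.7e-16, and adjusted p = 0.0154 with an estimated correlation), with Ccl6 at 8.90 and Il6 at 7.59, while 3 did not pass, Nos2 (-0.14), Il12b (-0.07) and Il10 (0.18), chosen after their values were seen. Of 14 Toll-like receptor genes 10 rose (10 adjusted over the list alone, adjusted p = 8.4e-08, and adjusted p = 0.0136 with an estimated correlation), Tlr2 (6.77) and Tlr13 (5.26) most. All 7 complement genes rose, also adjusted over the list alone (adjusted p = 2.9e-05, and adjusted p = 0.0154 with an estimated correlation), from C3ar1 at 7.47 and C1qb at 5.22.

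Lipid, adhesion and interferon groups rose as well. Of 14 lipid handling genes 10 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 7.7e-06, and adjusted p = 0.0447 with an estimated correlation), with the cholesterol exporter gene Abca1 at 5.59 and Lpl, lipoprotein lipase, at 4.66. Of 17 integrin and adhesion genes 12 rose (14 adjusted over the list alone, adjusted p = 1.2e-08, and adjusted p = 0.0119 with an estimated correlation), Itgb7 (5.09) and Itgb2 (4.33) most. Of 16 interferon-stimulated genes 9 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 5.6e-05, and adjusted p = 0.163 with an estimated correlation), with Rsad2 (3.72) and Ifih1 (3.71) highest. Of 15 glycolysis genes 8 rose (9 adjusted over the list alone, adjusted p = 0.00185, and adjusted p = 0.184 with an estimated correlation), of 5 NADPH oxidase genes 4 (4 adjusted over the list alone, adjusted p = 3.8e-04, and adjusted p = 0.148 with an estimated correlation) and of 13 apoptosis regulators 7 (8 adjusted over the list alone, adjusted p = 3.8e-04, and adjusted p = 0.045 with an estimated correlation), the last with Pmaip1 (2.43) and Cflar (2.32).

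All 19 G2 and mitosis genes fell by 120 h, also adjusted over the list alone (adjusted p = 1.3e-24, and adjusted p = 0.0119 with an estimated correlation), with Cdc20 at -6.93 and Top2a at -6.79. Of 26 S phase genes 25 fell (25 adjusted over the list alone, adjusted p = 1.3e-24, and adjusted p = 0.0119 with an estimated correlation), with Rrm2 at -7.29 and Mcm5 at -6.53. Of 20 Myc and ribosome biogenesis genes 19 fell (20 adjusted over the list alone, adjusted p = 4.6e-11, and adjusted p = 0.0517 with an estimated correlation), Nop56 most (-2.86). Of 14 sterol synthesis genes 11 fell (11 adjusted over the list alone, adjusted p = 1.1e-06, and adjusted p = 0.0136 with an estimated correlation), with Idi1 at -3.75 and Dhcr7 at -2.55. B lineage transcription factors fell in 15 of 16 cases (15 adjusted over the list alone, adjusted p = 1.4e-14, and adjusted p = 0.0119 with an estimated correlation), with Pou2af1 at -7.56 and Myb at -7.03. Of 18 B lineage surface genes 15 fell (15 adjusted over the list alone, adjusted p = 1.2e-09, and adjusted p = 0.0136 with an estimated correlation), such as Vpreb1, part of the surrogate light chain (-6.22), and 2 rose, Bst1 (2.69) and Ptprc (1.41), both chosen after their values were seen. Of 8 V(D)J genes 7 fell and 1 rose, also adjusted over the list alone (adjusted p = 1.2e-05, and adjusted p = 0.0205 with an estimated correlation). Il7r, which was at 6.25 at 48 h, had a mean of 10.12 at 120 h, beside 9.91 in vehicle and 10.82 in macrophages. Of 34 lists 23 passed, 16 with an estimated correlation, and with the run as a block 3107 genes rose and 3274 fell.

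Cultured macrophages differed from vehicle in a like number of genes, 2837 higher and 2512 lower, 1930 and 1390 of them by at least 2-fold. C1qb (Entrez 12260), a complement subunit made by macrophages, was at least 416-fold higher (log2 change 8.70 ± 0.19, SE, n = 2 arrays per group, adjusted p = 7.6e-10), Csf1r 509.5-fold (8.99 ± 0.38), Chil3, a chitinase-like protein gene, at least 324-fold (8.34 ± 0.19) and the mannose receptor gene Mrc1 at least 313-fold (8.29 ± 0.25). Vpreb1 was 428-fold lower (-8.74 ± 0.44), Enpep was at -8.44, Ebf1 at -7.95, Socs2 at -7.88 and Bach2 at -6.95, the last 4 at background in macrophages and so lower bounds of the fall. All 31 macrophage surface genes were higher (adjusted p = 1.1e-33, and adjusted p = 0.0108 with an estimated correlation) and all 23 lysosome genes (adjusted p = 5.0e-17, and adjusted p = 0.0318 with an estimated correlation), in both lists also adjusted over the list alone. Of the 5349 genes called in macrophages 98 had another probe set that passed in the opposite direction, the lysosome genes Neu1 and Npc2, chosen after their values were seen, among them. Of 9 MHC class II genes 5 were higher and 1 lower, also adjusted over the list alone (adjusted p = 0.00597, and adjusted p = 0.112 with an estimated correlation), with H2-DMa at 3.16 and H2-Aa at 2.59. Of 12 neutrophil granule genes 8 were higher (8 adjusted over the list alone, adjusted p = 5.7e-06, and adjusted p = 0.0245 with an estimated correlation), Chil3 and Mmp8 (6.51) most. Proliferation genes were modestly lower: 16 of 26 S phase genes (17 adjusted over the list alone, adjusted p = 4.0e-07, and adjusted p = 0.0318 with an estimated correlation), with Tyms at -3.92 and Orc1 at -2.10, and 11 of 19 G2 and mitosis genes (14 adjusted over the list alone, adjusted p = 2.5e-06, and adjusted p = 0.066 with an estimated correlation). Of 34 lists 26 passed, 15 with an estimated correlation, and with the run as a block 3199 genes were higher and 2947 lower.

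**Figure D3:**
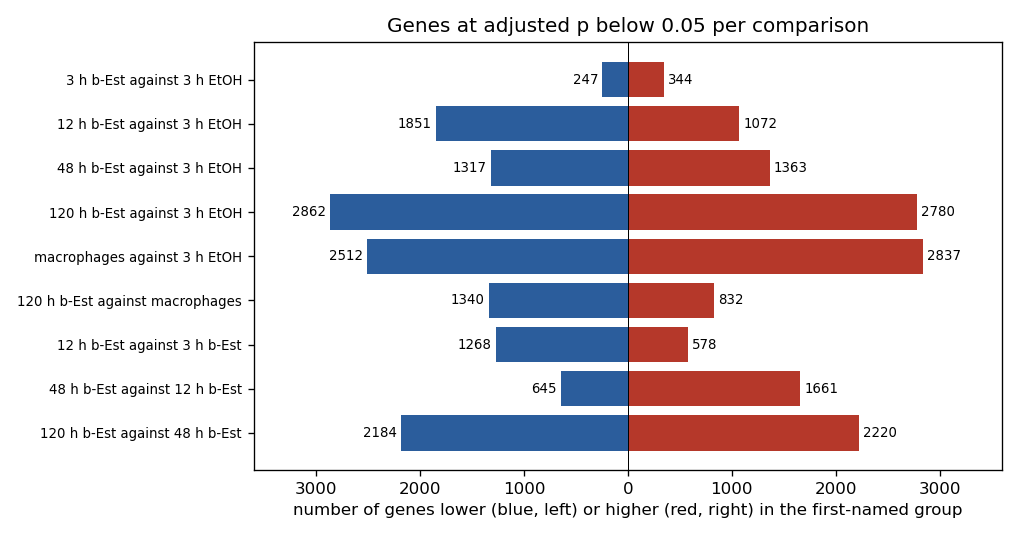
Number of genes (horizontal axis) at an adjusted p below 0.05 in each of 9 comparisons (vertical axis), lower in the first-named group to the left and higher to the right. The 3 h comparison has 591 such genes and the 120 h comparison with vehicle 5642.

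The direct comparison of 120 h cells with macrophages asked how close the induced cells came to the target cell type. The purity of the macrophage samples was not tested. Of 10 mast cell, basophil and eosinophil genes 6 were higher in them than in vehicle, so the differences below need not be those of macrophages alone. Inflammatory genes were higher in the 120 h cells: Il6 (Entrez 16193), a fever cytokine gene, by 81.7-fold (log2 difference 6.35 ± 0.23, SE, n = 2 arrays per group, adjusted p = 2.6e-08), Serpinb2 by 62.7-fold (5.97 ± 0.33) and the neutrophil chemokine gene Cxcl3 by 42.3-fold (5.40 ± 0.23). Cell cycle and antigen presentation genes were lower: Mki67 by 112-fold (-6.81 ± 0.18) and H2-Aa (Entrez 14960), an MHC class II chain, at -5.64 ± 0.20 on the log2 scale. Chil3 was at least 388-fold lower and the lectin gene Mgl2 101-fold lower. In all 832 genes were higher and 1340 lower at 120 h, 438 and 908 of them by at least 2-fold, against 5642 genes that separated 120 h cells from vehicle.

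Of 21 cytokine and chemokine genes 13 were higher at 120 h (14 higher adjusted over the list alone, adjusted p = 2.2e-14, and adjusted p = 0.0423 with an estimated correlation), with Il1b at 4.71, Il1a at 4.03, Ptgs2, the inducible prostaglandin synthase gene, at 3.06 and the list median at 1.20. Of 9 MHC class II genes 7 were lower (8 adjusted over the list alone, median -2.09, adjusted p = 1.5e-10, and adjusted p = 0.0178 with an estimated correlation), with H2-Eb1 at -4.49, H2-Ab1 at -3.94 and Cd74 at -2.19. All 19 G2 and mitosis genes were lower, also adjusted over the list alone (median -4.58, adjusted p = 5.2e-43, and adjusted p = 0.00379 with an estimated correlation), as were 23 of 26 S phase genes (24 adjusted over the list alone, median -3.19, adjusted p = 1.1e-36, and adjusted p = 0.00379 with an estimated correlation), with Rrm2 at -6.17, Top2a at -5.91 and Ccne2 at -5.66. Of 14 sterol synthesis genes 11 were lower (13 adjusted over the list alone, median -1.57, adjusted p = 1.5e-10, and adjusted p = 0.00749 with an estimated correlation), with Idi1 at -2.92 and Fdps at -2.40. These 5 lists were the ones that passed with an estimated correlation, of 12 that passed.

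Several macrophage groups were split between the 120 h cells and macrophages. Of 31 macrophage surface genes 5 were higher and 11 lower at 120 h (8 and 11 adjusted over the list alone, adjusted p = 0.185). The fractalkine receptor gene Cx3cr1 (-4.50), Itgax (-2.74) and Axl (-2.49) were lower. Of 7 complement genes 4 were lower (4 adjusted over the list alone, adjusted p = 0.0129, and adjusted p = 0.137 with an estimated correlation), C1qc at -5.53 and C1qa at -3.85, and Cfp, properdin, chosen after its values were seen, was higher (1.51), although another of its probe sets passed in the opposite direction. Of 21 myeloid transcription factors 7 were higher and 2 lower (8 and 3 adjusted over the list alone, adjusted p = 0.00124, and adjusted p = 0.332 with an estimated correlation), with the immediate early gene Egr1 at 3.37 and Pparg at -1.82. Of 14 Toll-like receptor genes 3 were higher, Tlr2 most (2.97), and 2 lower, Tlr1 most (-2.08). Of 23 lysosome genes 4 were lower, Atp6v0d2 most (-2.77), and 19 did not pass. Of 14 lipid genes 2 were higher and 5 lower, with Pltp (-2.48) and Fabp4 (-2.05) lowest. Ccn3 (7.90), the carbonic anhydrase gene Car6 (7.40), Cav1, a caveolae protein gene (5.99), Scel (5.70) and Cnn3 (5.58) had the largest other excesses at 120 h.

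Single B lineage genes differed between 120 h cells and macrophages, while neither B lineage list passed. Of 16 B lineage transcription factors 1 was higher and 1, Irf4 (-2.43), lower, and 14 did not pass (adjusted p = 0.707). Among 18 B lineage surface genes 3 were higher and 4 lower, with Vpreb1 at 2.52 and Cd72 at -2.95 (adjusted p = 0.658 for the list). Ighm, chosen after its values were seen, had a mean of 5.97 ± 0.03 (SD) at 120 h and 11.11 ± 0.25 in macrophages, beside 14.14 ± 0.01 in vehicle. With the run as a block 1115 genes were higher and 1755 lower, and the count of 2172 became 1324 without the second macrophage array. With the arrays centred on reference genes 1219 genes were higher and 901 lower, and the median difference of all genes was 0.25.

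**Figure D4:**
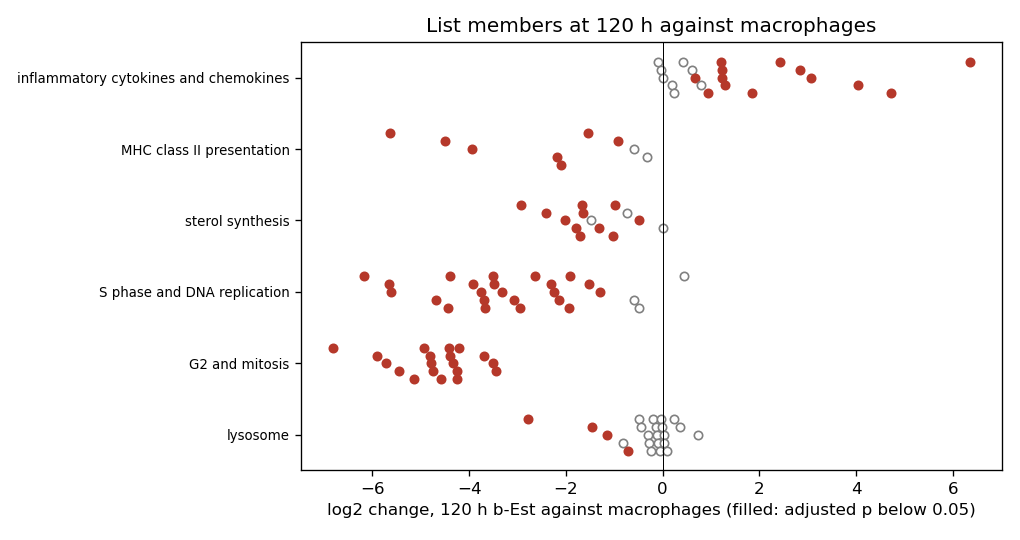
Log2 change of each member (horizontal axis) of 6 gene lists (vertical axis) at 120 h against macrophages, with filled dots for members at an adjusted p below 0.05. The 19 G2 and mitosis genes all lie below 0, 13 of 21 cytokine genes are filled and above 0, and 19 of 23 lysosome genes are open.

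The last step between successive times held the most genes in the reported fit, but this order depended on the 12 h arrays and on the scaling. From 3 to 12 h 578 genes rose and 1268 fell, from 12 to 48 h 1661 rose and 645 fell, and from 48 to 120 h 2220 rose and 2184 fell. Prtn3 (4.28 ± 0.16, SE, n = 2 arrays per group, adjusted p = 1.1e-06) and Tgfbi (4.06 ± 0.20) led the rise from 3 to 12 h, and Mpzl2 (-4.26) and P2ry10 (-4.18) the fall. Ms4a6d (5.45 ± 0.14), Cd14 (5.12), Lpl (5.08) and Il6 (4.96) rose from 12 to 48 h, while Steap4 (-4.88) and Tmcc3 (-3.20) fell. The collagenase gene Mmp13 (8.63 ± 0.22), Cxcl2 (8.10), Saa3 (7.45) and Arg1, arginase (7.01), rose from 48 to 120 h, while Mki67 (-7.16), Rrm2 (-7.01) and Prtn3 (-6.46) fell. In that last step all 19 G2 and mitosis genes fell (adjusted p = 2.2e-29, and adjusted p = 0.00987 with an estimated correlation), 25 of 26 S phase genes fell (adjusted p = 3.5e-28, and adjusted p = 0.0085 with an estimated correlation), and 18 of 21 cytokine genes rose (adjusted p = 3.7e-15, and adjusted p = 0.0258 with an estimated correlation), the same numbers adjusted over each list alone. From 12 to 48 h 21 of 31 macrophage surface genes rose (23 adjusted over the list alone, adjusted p = 3.8e-21, and adjusted p = 0.0798 with an estimated correlation).

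Both steps that use the 12 h arrays depend on them. With only the 4 arrays compared 56 genes rose and 84 fell from 3 to 12 h, and 553 rose and 163 fell from 12 to 48 h. With array weights the numbers were 162 and 433, and 842 and 278. The steps span 9, 36 and 72 h, and their counts of 1846, 2306 and 4404 genes became 6628, 6014 and 4088 with reference genes and 5110, 4638 and 5068 without the first 12 h array, where the last step was no longer the largest. The step from 3 to 12 h had 1065 genes higher and 2075 lower with the run as a block, 344 and 734 without the second 12 h array (1078 in all, 827 of the 1846 called in both fits), 2657 and 2453 without the first 12 h array (5110 in all), and 451 and 366 in all without the first and the second 3 h array. The step from 12 to 48 h had 2427 higher and 971 lower with the run as a block, 1265 and 613 without the second 12 h array (1488 of the 2306 called in both fits), 2521 and 2117 without the first 12 h array (4638 in all), and 1317 and 1029 in all without the first and the second 48 h array. Their splits followed the scaling too: from 3 to 12 h 826 rose and 723 fell after quantile normalization, 306 and 1694 after median centring, 645 and 728 after cyclic loess and 6115 and 513 with reference genes (median of all genes 0.51), and from 12 to 48 h the numbers were 1247 and 957, 1885 and 407, 1188 and 842, and 736 and 5278 (median of all genes -0.50). The step from 48 to 120 h had 2567 higher and 2632 lower with the block, and with reference genes 2471 and 1617 (median of all genes 0.14).

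A set of genes rose at 12 or 48 h and then fell again. Transient here means higher than vehicle at 12 or 48 h and lower at 120 h than at that time, both at an adjusted p below 0.05. Prtn3 was the clearest, with means of 6.19 ± 0.09 (SD, n = 2) in vehicle, 10.63 ± 0.12 at 12 h, 12.93 ± 0.21 at 48 h, 6.46 ± 0.04 at 120 h and 6.36 ± 0.23 in macrophages. Crispld2 (10.60 at 48 h, 5.70 at 120 h), Ms4a4b (9.24 and 4.55) and Ifitm1 (13.11 and 10.33) peaked at 48 h as well, and Fbp1, an enzyme of gluconeogenesis, had 8.81 at 12 h and 4.84 at 120 h. Steap4, a metal reductase gene, had 9.52 at 12 h and 4.64 at 48 h. Nfe2, Il6ra, Tmcc3, Dgat2, Baiap3 and Fes were also among the 10 largest at 12 h, as were Tgfbi, Hp, Emb, Gpr84, Papss2 and Svip at 48 h. In all 611 genes were transient, 392 at 12 h and 294 at 48 h with 75 at both, and 84 were still above vehicle at 120 h. Of 10 progenitor and primary granule genes 4 were transient (Prtn3, Ctsg, Ms4a3 and Gfi1). Of 12 neutrophil granule genes 3 were, all at 12 h only, of 17 integrin and adhesion genes 3 (Itgal, Itgb3 and Vcl), and of 24 stem and multipotent progenitor genes 2 (Flt3 and Runx1), also at 12 h only. Of 11 T cell genes 2 were transient and of 14 sterol synthesis genes 2, and each other list had at most 1. Both calls of a transient gene use the same 12 or 48 h arrays, so an error of those arrays enters both. Of the 392 genes transient at 12 h 133 were among the dimmest 40 percent of genes, against 41 of the 232 without the second 12 h array and 24 of the 294 transient at 48 h. With the block 941 genes were transient, and without the second 12 h array 533, of which 232 at 12 h with 162 called in both fits. After centring on reference genes 2185 were transient, and after median centring 389. The number was 2184 without the first 12 h array, 380 and 289 without the first and the second vehicle array, and 386 without the second 120 h array.

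Most genes that set macrophages apart from vehicle had moved the same way by 120 h. Of the 2837 genes higher in macrophages 2139 were also higher at 120 h, against 433 with independence, and of the 2512 lower genes 1985 were also lower, against 395. Both comparisons use the same 2 vehicle arrays, which were not split, so part of the excess can come from them. In simulated data without effects the mean overlap was 0, since almost no gene is called there, and this 0 does not measure what the shared arrays add. Across all genes the changes correlated at r = 0.838, against 0.501 in those simulations (genes are not independent replicates), with a covariance of 1.20 against 0.0233. The 0.501 follows from the shared vehicle arrays where no gene changes, so it is no floor for r where genes do change. Of the 4124 shared genes 1018 still differed between 120 h cells and macrophages, 394 higher and 624 lower at 120 h, and 3106 did not pass. Of the 2139 shared higher genes 173 had passed in the same direction at 3 h, 404 at 12 h (361 without the second 12 h array) and 973 at 48 h, while 27, 143 and 49 had passed in the opposite direction. Of the 1985 lower genes 174, 889 (644) and 814 had passed in the same direction and 38, 33 and 20 in the opposite one. Of the genes higher at 3 h 207 of 344 were also higher at 120 h, against 53 with independence, and 52 were lower. Of those lower at 3 h 184 of 247 were also lower, against 39, and 33 were higher. For this pair r was 0.322, and the 0.50 of the simulations without effects is likewise no floor for it. The covariance was 0.147 against 0.0232, and the same vehicle arrays are shared.

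Over the 5349 genes that differed between macrophages and vehicle, each array was placed on a line from the vehicle mean at 0 to the macrophage mean at 1. The 3 h arrays stood at a mean of 0.104 ± 0.0042 (SD, n = 2), the 12 h arrays at 0.224 ± 0.0080, the 48 h arrays at 0.457 ± 0.019 and the 120 h arrays at 0.917 ± 0.033. The differences between successive times were larger than the spread between replicates. The vehicle and macrophage arrays both chose the genes and set the end points. Their error is shared by all b-Est arrays and is not part of that spread.

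**Figure D5:**
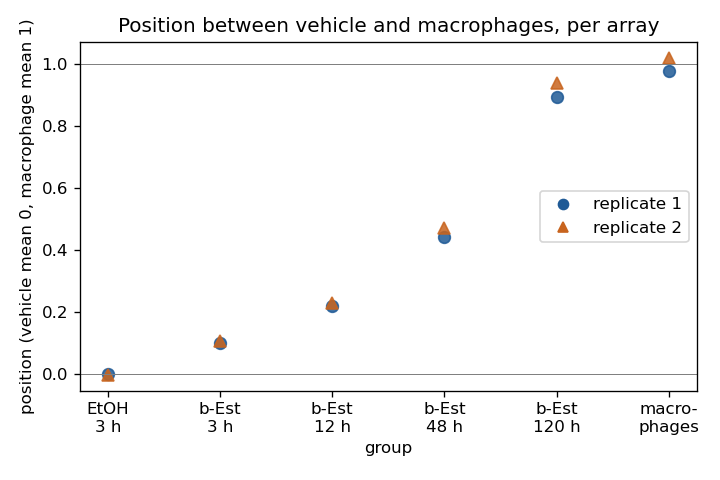
Position of each of the 12 arrays (vertical axis, vehicle mean 0, macrophage mean 1, no unit) by group (horizontal axis), with circles for replicate 1 and triangles for replicate 2. The 48 h arrays stand at 0.443 and 0.471 and the 120 h arrays at 0.894 and 0.940.

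Most genes of other cell types did not pass at 120 h, but most of those that did changed strongly. Of 98 genes in these lists 20 passed against vehicle, 18 of them by at least 2-fold. Among all 18194 genes 5642 passed (31.0%), 3741 of them by at least 2-fold, so most genes of any kind did not pass. The platelet gene Vwf (5.96) and the bone protease gene Ctsk (4.15) were among those that rose. Of 9 NK cell genes 0 passed at 120 h against vehicle with limma over all genes, adjusted over the list alone or at an unadjusted p below 0.05. Of 11 T cell genes 1 was higher, Cd28 (1.14), and 1 lower, Thy1 (-2.74), which had stood at 1.97 at 48 h. Of 9 erythroid genes 1 fell, Car2, a carbonic anhydrase also made by other cells (-5.21), and of 9 dendritic cell genes 1 rose and 2 fell, Btla most (-4.12). Of 9 mature B and plasma cell genes 2 fell, Ms4a1 (-6.44) and Cxcr5 (-3.54), and 1 rose. Of 8 pluripotency genes 0 passed at 120 h with limma in any of these 3 ways, Nanog (0.13) and Sox2 (-0.08) among them. Of 24 stem and multipotent progenitor genes 2 rose, Procr (2.44) and Lmo2 (2.17), and 1 fell, Mycn (-2.30). At each time most of the 17 stromal fibroblast genes did not pass. Of the 17 5 were lower and 1 higher at 12 h, 5 were lower and 1 higher at 48 h, with falls such as Cxcl12 (-2.87) and Col1a2 (-2.82). At 120 h 3 were lower and 2 higher, and 6 were lower in macrophages, Col1a2 at -4.16.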

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

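The tests of weak hybridisation, degraded RNA, time in culture, stromal cells, processing run and scaling as causes were chosen only after the result was seen. The group comparisons, the list tests and the 4 other scalings themselves were set before. The test of a culture further along the time course was set before its own value was seen. It names the second 12 h array, so it was not set before that array was singled out.

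The second 12 h array differed from its partner more than any other replicate did: the SD over genes of its difference, less the mean difference of the other 5 groups, was 0.525, against 0.262 to 0.311 for the plain differences in those groups. Degraded RNA on the second 12 h array is argued against by the 3′ minus 5′ difference of the actin controls. It was 1.98 and lay inside the 1.64 to 2.34 of the other arrays of its run. The first 12 h array was not tested: it read 4.22, the highest of all arrays, so lower RNA quality there is left open. A culture further along the time course is argued against by r = 0.0257 across genes (which are not independent replicates) between the deviation and the change from 3 to 48 h, below the bound of 0.1 set beforehand. Weak hybridisation of the second 12 h array may account for the difference, but its test could not decide this. Its 4 hybridisation controls averaged 10.4, against 10.7 to 11.2 on the other 11 arrays. Of these controls bioC read 9.61, inside the range of 9.54 to 10.2. The controls were read after RMA. On this array the range was narrow and brighter genes read lower, so bright controls would read low whatever the cause. The poly-A controls dap (9.16) and thr (7.98), which are not hybridisation controls, were also the lowest of the arrays numbered 2. No other biological explanation was tested.

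The cell cycle lists were lower at 120 h than in macrophages, which stood out because the difference between these groups was tested and passed: the median difference was -4.58 for G2 and mitosis genes and -3.19 for S phase genes. The scaling of the arrays as the whole cause is argued against by the 4 other scalings, under which the median of the G2 and mitosis list was -4.33 or lower, down to -4.61. Time in culture cannot be told apart from b-Est, since there were 0 vehicle arrays at 120 h. Differences between the cultures of the induced cells and of the macrophages, or in their origin or purity, could contribute as well and were not tested.

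The cytokine and chemokine list was higher at 120 h than in macrophages, with a median difference of 1.20 that passed the test. Each run held arrays of both groups, so a run difference shared by all groups cancels in this comparison, and the test could not detect one. The median difference over all 21 measured members was 1.08 in the run with the smaller value and 1.19 in the other, so it did not rest on 1 run. The scaling of the arrays is argued against by the 13 to 15 members called under the 4 other scalings. Stromal cells carried through the GFP sort in larger number at 120 h cannot be told apart from a change in the sorted cells: of 17 stromal genes 5 were higher at 120 h than in macrophages, such as Col1a2 (2.94), and the 12 below 7 on the log2 scale in vehicle went both ways at 120 h against vehicle, from -1.30 to 1.04 with a median of -0.0686. An earlier form of this test, on the 6 stromal genes lower in macrophages than in vehicle, gave a median of -1.16 (median SE 0.33) at 120 h against vehicle, beside 4.18 for the 13 called cytokine genes, and does not decide it either, since those genes were chosen by their values. A response of the cells to changed stroma, or a difference in origin, culture or purity between them and the macrophages, could underlie the pattern and was not tested.

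Other differences between 120 h cells and macrophages that passed a test of the difference were a median of -2.09 for MHC class II genes and of -1.57 for sterol synthesis genes. There were 37 genes lower at 120 h and higher in macrophages than in vehicle, H2-Aa and Hdac9 among them, and 26 genes higher at 120 h and lower in macrophages, Egr1 and Ccn3 among them, each with the direct difference also past the test. The dap control, outside the gene comparisons, averaged 10.3 on the 6 arrays numbered 2. Among 10092 probe sets with no gene name or several, controls left out, 1760 passed at 120 h against vehicle, 584 higher and 1176 lower.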

How the results depend on the processing

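Array weights, and the replicate block without the second 12 h array, were chosen only after the data were seen, and all other alternatives in this part were planned. For named genes, 11110 values kept their direction and side of the threshold under alternatives other than leaving out an array, 450 kept the direction and no longer passed, 9 newly passed and 4 reversed, and for lists 1152 kept both and 44 no longer passed. Leaving out single arrays kept 11224 gene values and 1277 list values, while 738 and 31 no longer passed and 2 gene values newly did. With 1 array left in a group, its spread is taken to be that of the other groups. The 4 reversals came when probe sets shared between transcripts were left out: Acta2 was at -0.042 at 120 h against vehicle, -0.038 against macrophages and -0.206 against 48 h, and Igll1 at 0.342 at 120 h against 48 h. These use another probe set of the gene, and the cause was not tested.

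Counts of genes that left the range of 1.5 times the reported one were as follows, and except where fewer genes (the 2-fold limit), more features (all probe sets) or fewer arrays were the change itself, the cause was not tested. With all probe sets tested singly the counts were 1010 at 3 h, 5458 at 12 h, 5465 at 48 h and 11329 at 120 h against vehicle, 11219 for macrophages against vehicle, 4142 for 120 h against macrophages, and 2770, 3569 and 7851 for the 3 successive steps. With a change of at least 2-fold they were 1285 at 12 h, 1592 at 48 h and 3741 at 120 h, 3320 for macrophages, 1346 for 120 h against macrophages, and 778, 1162 and 2678 for the steps. Centring on reference genes gave 7811 at 12 h, 6628 and 6014 for the steps into and out of 12 h, and 2185 transient genes, and median centring 389 transient genes. Only the arrays compared gave 700 at 12 h, and 140 and 716 for the steps into and out of 12 h, and array weights gave 1202, 595 and 1120. The replicate block gave 3140 for the step from 3 to 12 h and 941 transient genes, and together with leaving out the second 12 h array 1354 at 3 h, 4769 at 48 h, 4071 for 120 h against macrophages and 986 transient genes. The position of the 12 h arrays, 0.224, was 0.216 after quantile normalization, 0.21 after median centring, 0.253 with reference genes and 0.233 with the mean of probe sets.

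Leaving out each array in turn gave 281 to 774 genes at 3 h, 913 to 5971 at 12 h, 1653 to 3326 at 48 h, 4483 to 6294 at 120 h, 4083 to 5967 for macrophages, 1324 to 2754 for 120 h against macrophages, 366 to 5110 from 3 to 12 h, 1029 to 4638 from 12 to 48 h and 3153 to 5068 from 48 to 120 h. It gave 289 to 2184 transient genes, 3157 to 4714 genes changed the same way at 120 h and in macrophages, and 150 to 164 list calls over the 9 comparisons, against 157. The positions ranged over 0.1 to 0.118 at 3 h, 0.202 to 0.25 at 12 h, 0.443 to 0.471 at 48 h and 0.878 to 0.94 at 120 h. Same-numbered arrays of 15 pairs of groups correlated, after group means were taken out, at r = -0.0985 to 0.532 (12 above 0.1), at 0.231 or more without the 12 h arrays and at 0.337 or less with them, across genes, which are not independent replicates. The rule set for pairing asked for every pair above 0.1, which was not met, so the reported fit has no block. However, 12 of 12 arrays correlated more on average with arrays of their own number, which the dap control ties to a processing run. The spread behind the reported p-values therefore includes the run difference. Another probe set passed in the opposite direction for 0 of the genes called at 3 h, 18 at 12 h, 6 at 48 h, 48 at 120 h and 3 at 120 h against macrophages. Signal near background limits what dim genes can show: probe sets of Y-linked genes read 3.47 to 4.59 here.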

Other observations

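Transcripts of megakaryocytes, mast cells and basophils were found in part in the macrophages. Pf4, a platelet chemokine gene, was at 7.24 (log2 change against vehicle) in macrophages and 5.78 at 120 h, and Vwf, von Willebrand factor, at 5.14 and 5.96. Of 8 megakaryocyte and platelet genes 4 were higher in macrophages and 3 at 120 h, the same numbers adjusted over the list alone, while Gp9 (0.05), a platelet receptor gene, did not pass at 120 h. Of 10 mast cell, basophil and eosinophil genes 6 were higher in macrophages than in vehicle (6 adjusted over the list alone, adjusted p = 0.00281, and adjusted p = 0.225 with an estimated correlation), led by Cpa3, a mast cell protease (4.33), Ms4a2 (2.33) and Prg2, an eosinophil granule protein (2.13). At 120 h 5 of the 10 were lower than in macrophages (6 adjusted over the list alone, adjusted p = 5.8e-05, and adjusted p = 0.242 with an estimated correlation). The progenitor genes Cd34 (2.64) and Tal1 (2.92) were higher in macrophages than in vehicle too. Of 12 neutrophil granule genes 6 were lower at 120 h than in macrophages and 2 higher, with Padi4 at -3.48 and S100a8 at -2.55.

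Regulators of DNA methylation and chromatin moved over the course. Of 14 measured, 10 fell by 120 h and 1 rose (11 and 1 adjusted over the list alone, adjusted p = 4.1e-06, and adjusted p = 0.0136 with an estimated correlation). Uhrf1 (-6.25) and Dnmt1 (-3.43), which maintain methylation, and Ezh2 (-4.28), a histone methyltransferase, fell. In the same comparison 25 of 26 S phase genes fell, and whether the falls of these regulators are separate from that was not tested. Tet2, which oxidises methylated cytosine, rose at 12 h (1.73 ± 0.20) and 48 h (1.63 ± 0.20). At 120 h Tet2 was still above vehicle, whereas in macrophages it was below vehicle. Of 20 Myc and ribosome biogenesis genes 19 were lower in macrophages than in vehicle (19 adjusted over the list alone, adjusted p = 3.1e-11, and adjusted p = 0.0503 with an estimated correlation), with Nop56 at -2.50. Of 8 osteoclast genes 2 rose and 1 fell by 120 h, with the bone protease gene Ctsk at 4.15, and 4 were higher and 1 lower in macrophages, with Ctsk at 2.07.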
